A study of Mus musculus with 9 samples.

How the data were processed

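The series measured gene expression in erythroblasts, the nucleated precursors of red cells, on 9 single-colour arrays. Per the labels, the cells were sorted from the bone marrow of wild-type C57BL/6J mice labelled female. There were 3 groups of 3 arrays each: normal diet, 3 weeks of low iron diet and 7 weeks of low iron diet, both started after weaning. The design text calls the 3 samples of a group biological replicates, so the p-values measure the spread between samples of different animals or pools; whether a sample came from 1 animal or from several is not stated in the labels. The age of the normal diet mice was not given in the sources used here.

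Per the labels' protocols, total RNA was extracted with a micro-scale column kit, amplified to aminoallyl RNA and coupled to Cy3. The deposited scanner files hold the intensity of each spot as Agilent Feature Extraction 10.7.3.1 wrote it, per the file headers: background-subtracted and detrended within the array, with no scaling between arrays. The deposited series table holds log2 values of the same arrays for 34922 probes. Compared with the scanner intensities, it was centred on each probe's median over the 9 arrays, with r between 0.997 and 0.999 and slopes from 0.995 to 1, so scale and direction were settled from the data; the normalization between arrays before centring was not given. Each array's median in it was 0, except -0.019 for 7 week replicate 2.

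Each array held 62976 spots, 59305 of them not controls, for 55681 probes. Spots marked as outliers by the scanner software were left out, and no spot was marked saturated. A ceiling on the signal of the brightest probes would let a lower 75th percentile raise their scaled values; whether there was one was not tested. After the results were seen, the change in signal before scaling was set beside each gene's signal in percent of the saturation value (geometric mean over the 9 arrays). The log2 processed signal minus the array's 75th percentile of it was averaged over the spots of a probe. Probes were named by matching their RefSeq accession, without version, to a gene table of assembly GRCm38.p6, which was used only for names, chromosomes and gene spans. This named 26413 probes with 20018 symbols; 26403 of the 27016 probes carrying a RefSeq transcript accession matched, and 29268 probes stayed unnamed and entered no main comparison. A probe was tested when it was well above background on all 3 arrays of at least 1 group, which 34837 probes were. For each gene the probe with the brightest mean over the 9 arrays stood for it, which left 14506 genes; 984 probes had no usable spot on some array and were left out. Probes of a gene that went against the chosen probe past the threshold are counted with each comparison.

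The 3 comparisons (3 weeks against normal diet, 7 weeks against normal diet, and 7 against 3 weeks of low iron diet) were fitted in 1 linear model over all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. In the text, a gene's value is its log2 fold change ± the standard error of limma, from 3 arrays in each group, followed by the adjusted p. Where every array of a group was not well above background for a gene, the fold is a bound: the mean of the bright group against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own. A fitted log2 fold change given beside such a fold is no bound. Where only some arrays of a group were well above background, the fitted value is given.

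There were 29 gene lists, tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists, and repeated with a correlation estimated from the data and with fry. Of these, 23 were of processes: heme synthesis and porphyrin transport; globins and globin chaperone; iron uptake, storage and export; iron-sulfur cluster assembly; Bach1 and Nrf2 targets and antioxidant genes; mitophagy and autophagy; oxidative phosphorylation, mitochondrial ribosomal proteins, cytosolic ribosomal proteins, glycolysis, hypoxia-inducible genes, integrated stress response and Atf4 targets, erythropoietin and Stat5 response, erythroid transcription factors, red cell membrane and late maturation, progenitor and early erythroid genes, S phase genes, G2 and M phase genes, p53 targets and apoptosis, interferon-stimulated genes, cholesterol synthesis, heat shock and chaperone genes, and immediate early genes. The other 6 were markers of cells a marrow sort could hold: neutrophil lineage, monocytes and macrophages, B lineage, T and NK cells, megakaryocytes and platelets, and mast cells, basophils and eosinophils. A list's shift is its median log2 fold change minus that of all genes. Outside the plan, each list's median was also placed among 10000 random lists of the same size, drawn from genes of like brightness in 50 classes. These draws took genes as independent, so their range is too narrow for lists whose members vary together.

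The groups, tests, gene lists, threshold and the rule for the genes named were chosen before the data were examined. The rule takes, among genes past the threshold whose 3 arrays of 1 group all lie beyond the 3 of the other, the 10 largest rises and 10 largest falls of each comparison against normal diet, and the 5 and 5 largest between 7 and 3 weeks, passing over gene models without a usual name. It adds up to 4 members of each list past the threshold by size, or the 2 brightest members as values where fewer than 2 passed, and a fixed set of iron, heme, erythroid and stress genes whatever their result. Of that set, Hbb-b1 was not analysed here, and some genes that the rule takes are not reported here.

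Alternatives tried were quantile normalization, normexp background correction with an offset of 50, the deposited series table, no filter on dim probes, only probes above background on all 9 arrays, the mean over a gene's probes, the replicate number as a block, only the arrays of the 2 groups compared, a trend in eBayes, and leaving out each array in turn. The normexp alternative had been planned on mean spot signals; these files hold median spot signals, which were used in their place. After the sex-linked genes had been seen, 2 alternatives were added: keeping only normal diet replicate 3, the normal diet array with high Xist, and dropping genes on chromosomes X and Y. Slide and scan could not be entered as a block, because each group lies on 1 slide and in 1 scan of its own.

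The gene fit and the list test were tested on simulated data for 14506 genes with the measured means and spreads and 200 changed genes. For 3 weeks against normal diet, 4.55% of genes changed by 1 on the log2 scale, 44.8% of those changed by 2 and 86.6% of those changed by 4 were recovered; for 7 weeks against normal diet these shares were 6.06%, 59.7% and 89.6%. In each, 4 of the unchanged genes passed. A list of 17 genes moved by 1 passed in both, with the preset correlation (adjusted p = 6.1e-09 and 1.49e-14) and with an estimated one (adjusted p = 0.0261 and 0.0124), and 0 other lists passed in limma's camera. Genes were simulated as independent, so this does not test the list calls where members of a list vary together. With 3 arrays per group, the number of arrays limits the precision.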

Results

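Expression was measured in sorted bone marrow erythroblasts of mice on normal diet or on low iron diet for 3 or 7 weeks, with 3 arrays per group. The series is about iron deficiency anemia, mitophagy and gene expression in these cells, and each comparison with normal diet asks which genes differed after that time on the diet. Spots well above background made up 65.5% to 66.3% of each normal diet array, 56.8% to 70.8% at 3 weeks and 45.2% to 53.6% at 7 weeks. The 75th percentile of signal was 1499 to 1616, 1677 to 1837 and 791.7 to 1087. Spike-in controls, relative to that percentile, had a mean log2 level of 1.08 ± 0.62 (SD, n = 3) on normal diet, 1.34 ± 0.24 at 3 weeks and 4.97 ± 0.47 at 7 weeks. Arrays of a group correlated across genes at r of 0.981 to 0.987, 0.977 to 0.98 and 0.909 to 0.958, where genes are not independent replicates. Among the 7 week arrays, replicate 1 had the lowest mean r with its group (0.915, against 0.934 and 0.939 for replicates 2 and 3). Each group lay on a slide and in a scan of its own, so slide and group cannot be told apart in any comparison.

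The sex-linked genes set 2 normal diet arrays apart from their label. Normal diet replicates 1 and 2 had Eif2s3y, a Y-linked translation factor gene, at log2 levels of 5.12 and 4.82, and Ddx3y, a Y-linked helicase gene, at 1.90 and 0.88. On replicate 3 Eif2s3y, at -3.77, was still well above background and Ddx3y was not, and neither gene was on the 6 low iron arrays. Y-linked Kdm5d, at -7.52 and -7.56 on replicates 1 and 2, was not well above background on any array. Both probes of Y-linked Uty were on replicate 1 (-4.35 and -2.24), none was on replicate 2, and 1 was on 7 week replicate 3 (-1.67). Xist, the RNA that silences 1 X chromosome in females, was at -6.73 and -5.59 by its 2 probes on replicate 1 and at -4.82 and -5.24 on replicate 2, against -0.41 and -0.73 on replicate 3. On the low iron arrays the same probes lay between -2.06 and 1.46. By Xist, the comparisons with normal diet set 6 arrays with a high level against 1 such array and 2 with a low level, although all 9 are labelled female.

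**Figure D1:**
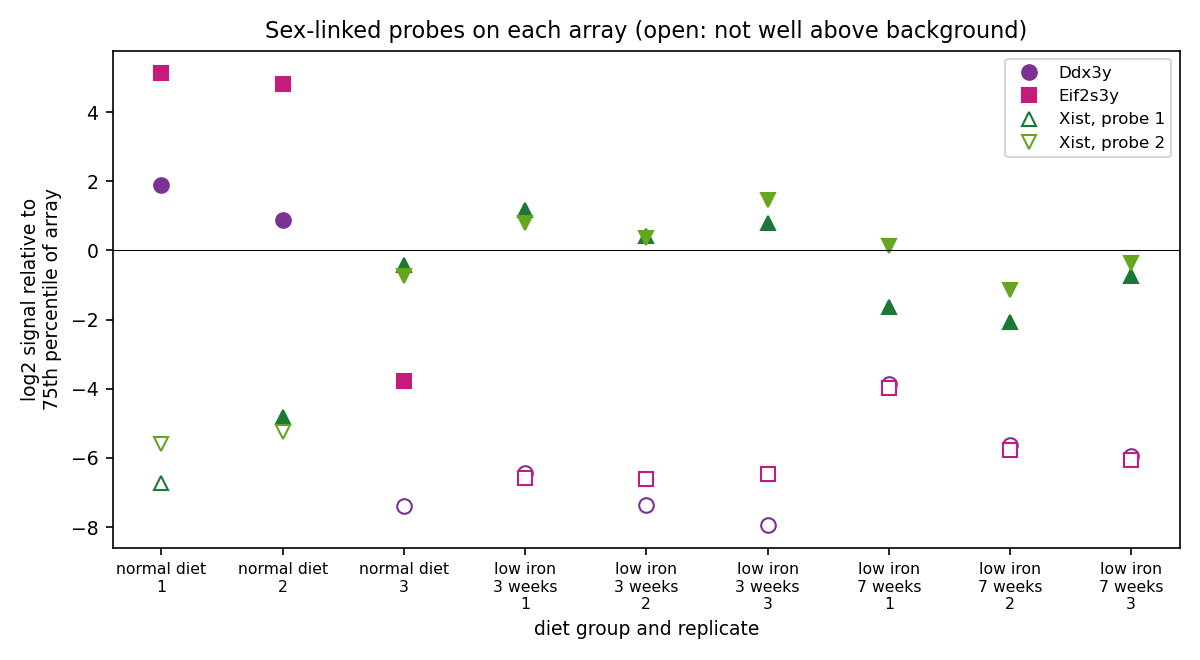
Level of Y-linked Ddx3y and Eif2s3y and of the 2 probes of X-linked Xist on each of the 9 arrays, as log2 signal relative to the array's 75th percentile; filled symbols are well above background and open ones are not. Eif2s3y reached 5.12 and 4.82 on normal diet replicates 1 and 2, where Xist lay at -4.82 or below.

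After 3 weeks of low iron diet, the sorted cells had more mRNA for the hormone erythroferrone, for some amino acid stress genes and for some markers of white cells, and less for part of the ribosomal proteins and of the respiratory chain, than on normal diet. The calls of these gene lists were lost with an estimated correlation (adjusted p from 0.728 to 0.888). Erfe, which encodes the erythroblast hormone that lowers hepcidin, rose (4.54 ± 0.43, adjusted p = 0.00794), as did Socs3, a feedback inhibitor of cytokine signalling (3.05 ± 0.52, adjusted p = 0.0134). Slc7a11, which imports cystine, rose at least 17.8-fold (5.87 ± 1.06, adjusted p = 0.015) and was not well above background on normal diet. Atp5k, a subunit of the mitochondrial ATP synthase, fell (-2.82 ± 0.44, adjusted p = 0.0108), and so did Rps21 of the small ribosomal subunit (-2.50 ± 0.41, adjusted p = 0.0121).

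Oxidative phosphorylation genes fell as a list at 3 weeks, with a shift of -0.96 (camera adjusted p = 2.85e-15, adjusted p = 0.728 with an estimated correlation). Of 75 measured members 40 fell and none rose (52 adjusted over the list alone). Besides Atp5k, the largest falls were of Uqcr10 of complex III (-2.39 ± 0.30, another probe at -0.35), Cox6c of complex IV (-2.14 ± 0.33) and Ndufa3 of complex I (-2.03 ± 0.28). Cytosolic ribosomal proteins fell, with a shift of -0.66 (adjusted p = 1.14e-14, adjusted p = 0.728 with an estimated correlation). Of 82 members 38 fell and none rose (50 adjusted over the list alone), among them Rpl38 (-2.12 ± 0.28) and Rpl36 (-1.88 ± 0.29) besides Rps21. Rps15a fell by its chosen probe (-1.98 ± 0.27), while another of its probes passed in the opposite direction. Mitochondrial ribosomal proteins fell, with a shift of -0.52 (adjusted p = 7.56e-04, adjusted p = 0.888 with an estimated correlation): 11 of 77 fell and none rose (12 adjusted over the list alone), with Mrps21 (-2.15 ± 0.27) and Mrpl52 (-1.92 ± 0.52) leading. Other genes of like brightness also had lower values at 3 weeks, with a median of -0.52 for random lists matched to the cytosolic ribosomal list and -0.56 for those matched to oxidative phosphorylation. With quantile normalization the shifts were -0.64 for oxidative phosphorylation and -0.32 for cytosolic ribosomal proteins.

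Integrated stress response and Atf4 target genes rose as a list at 3 weeks, with a shift of 1.46 (adjusted p = 8.13e-08, adjusted p = 0.728 with an estimated correlation). Of 32 measured members 7 rose and none fell (11 adjusted over the list alone). Besides Slc7a11, these were led by the stress-induced regulator Nupr1 (5.12 ± 1.37, adjusted p = 0.0445), by Cth, which makes cysteine (3.57 ± 0.50, adjusted p = 0.00926), and by the alanine aminotransferase gene Gpt2, at least 6.03-fold (3.18 ± 0.67, adjusted p = 0.0218). The usual readouts of this response had high values but a wide spread over the 9 arrays of the fit: Trib3 was at 3.96 ± 1.66 (adjusted p = 0.148), Chac1 at 3.88 ± 1.26 (adjusted p = 0.0772) and Ddit3 at 2.05 ± 1.19 (adjusted p = 0.282). Ddit3 and Chac1 had an SD of 2.92 and 2.76 on the 7 week arrays, which this comparison does not contrast. At 3 weeks the SD was 0.88 and 1.45, and on normal diet 0.27 and 0.94. Atf4 itself was at 0.08 ± 0.40 by its chosen probe and at 2.06 by another, and the heme-regulated kinase gene Eif2ak1 was at -0.39 ± 0.50 (adjusted p = 0.911 and 0.644 for the chosen probes).

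Some markers of other marrow cells were also higher at 3 weeks. The monocyte and macrophage list rose, with a shift of 1.08 (adjusted p = 6.51e-05, adjusted p = 0.728 with an estimated correlation): 4 of 15 rose and none fell (7 adjusted over the list alone), namely the lysozyme gene Lyz2 (3.59 ± 0.48), Cd14 (1.92 ± 0.36), Axl (1.5 ± 0.35) and the complement gene C1qa (1.38 ± 0.34). The B lineage list rose, with a shift of 1.47 (adjusted p = 0.00361, adjusted p = 0.728 with an estimated correlation), with 2 of 11 members rising, among them Ms4a1 (1.45 ± 0.38), and none falling (5 adjusted over the list alone). The neutrophil lineage list rose, with a shift of 0.96 (adjusted p = 0.0184, adjusted p = 0.835 with an estimated correlation), through the granule genes Mmp9 (3.52 ± 0.52) and Ngp (2.98 ± 0.50) among 17 members (2 adjusted over the list alone). That neutrophil call ended without normal diet replicate 1 or 3 or without 3 week replicate 2. Megakaryocyte, T and NK cell, and mast cell lists did not pass (adjusted p = 0.26, 0.122 and 0.71), with shifts of 1.09, 0.68 and -0.79 and no member past the threshold (0 adjusted over the list alone). Pf4 was at 1.06 ± 1.51 and Gp9 at -0.50 ± 0.52, Cd4 at 0.80 ± 0.42 (another probe at -0.47) and Lck at -0.19 ± 0.37, Prss34 at -1.15 ± 1.17 and Prg2 at -1.86 ± 1.39.

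The iron, heme and globin lists did not pass camera at 3 weeks. In the iron list 2 of 23 rose, Erfe and Exoc6, which serves transferrin receptor recycling (1.76 ± 0.48, adjusted p = 0.0475), and none fell (list adjusted p = 0.566, 1 adjusted over the list alone). Tfrc, the transferrin receptor gene, was at 0.35 ± 0.43, Slc40a1, the iron exporter gene, at -0.61 ± 0.30, and the ferritin genes Fth1 and Ftl1 at -0.34 ± 0.24 and -0.21 ± 0.25. None passed. In the heme list (adjusted p = 0.981) Cpox alone of 13 changed and fell (-1.36 ± 0.26, adjusted p = 0.0179; 1 adjusted over the list alone), while Alas2, the rate-limiting erythroid enzyme of heme synthesis, was at -0.09 ± 0.26 and Urod at -0.59 ± 0.27. No globin list member of 7 passed (list adjusted p = 0.231): Hba-a1 was at -0.34 ± 0.26 and Hbb-bt at -0.22 ± 0.25. The other list test, fry, called the globin list lower (adjusted p = 0.00544, with a range of 0.00544 to 0.728 over its alternatives), and 0 of the 7 lay above the median of all genes. Their median of -0.34 lay within the central 95% of random lists of like brightness (-0.89 to 0.06). The heme list's median of -0.09 lay above the central 95% of random lists of like brightness (-0.88 to -0.27). In the iron-sulfur cluster list 2 of 23 fell (adjusted p = 0.981, 2 adjusted over the list alone), among them the assembly factor Bola3 (-1.91 ± 0.29).

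Mitophagy and autophagy genes had a shift of 0.35 at 3 weeks that did not pass (adjusted p = 0.271). Their median of 0.18 lay above the central 95% of random lists of like brightness (-0.55 to -0.01). Of 45 members 2 fell and none rose (2 adjusted over the list alone), among them the mitofusin gene Mfn2 (-1.43 ± 0.33, adjusted p = 0.0275), for which another probe had 0.38. Bnip3l, the receptor that clears mitochondria from maturing red cells, was at -0.12 ± 0.27. Among hypoxia-inducible genes (adjusted p = 0.0592, 1 of 18 rose, 0 adjusted over the list alone) Egln3 rose (1.80 ± 0.47, adjusted p = 0.0396), and Bnip3 and Higd1a were at 0.60 ± 0.30 and -1.0 ± 0.31, with another Bnip3 probe at 3.14. Glycolysis genes (adjusted p = 0.108) had 1 rise and 1 fall among 17 (2 adjusted over the list alone), in Pfkp (3.20 ± 0.45) and Hk1 (-1.30 ± 0.23), both with a further probe of opposite sign, at -0.91 and 0.63. Antioxidant genes (adjusted p = 0.795) had a rise of Slc7a11 and a fall of the thioredoxin gene Txn1 (-1.10 ± 0.25) among 23 (3 adjusted over the list alone). Hmox1 was at 0.76 ± 0.39 and Bach1 at -0.20 ± 0.48.

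Lists of erythroid regulators did not pass at 3 weeks. In the erythropoietin and Stat5 list 3 of 16 rose (adjusted p = 0.0981, 4 adjusted over the list alone), Erfe, Socs3 and the kinase gene Pim3 (1.41 ± 0.32), and the receptor gene Epor was at -0.15 ± 0.30. Among erythroid transcription factors (adjusted p = 0.544) 2 of 16 fell, Zfpm1, the Gata1 partner (-1.58 ± 0.23), and E2f4 (-1.79 ± 0.39), with 3 adjusted over the list alone. Gata1 was at -0.34 ± 0.30 and Klf1 at -0.28 ± 0.31. Red cell membrane genes (adjusted p = 0.734) had a rise of the spectrin gene Sptb (3.14 ± 0.42) and a fall of the water channel gene Aqp1 (-1.04 ± 0.25) among 24 (2 adjusted over the list alone). Progenitor genes (adjusted p = 0.501) had a rise of Myc (1.45 ± 0.38) and a fall of Itga4 (-1.28 ± 0.31) among 15 (2 adjusted over the list alone), with another Itga4 probe at 0.51.

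The remaining process lists did not pass at 3 weeks. Immediate early genes (adjusted p = 0.128) had a rise of Ier2 (2.22 ± 0.58) and a fall of Jund (-1.78 ± 0.33) among 13 (2 adjusted over the list alone). Among p53 targets (adjusted p = 0.404) the apoptosis gene Bax fell (-1.16 ± 0.31), 1 of 17 (0 adjusted over the list alone). Btg2 was at -0.52 ± 0.46 and Sesn1 at -0.89 ± 0.40. No member passed among 18 interferon-stimulated genes (adjusted p = 0.164), 20 cholesterol synthesis genes (adjusted p = 0.981) or 12 heat shock genes (adjusted p = 0.231), with 0 adjusted over the list alone in each. Isg15 was at 0.39 ± 0.45, Rsad2 at -0.09 ± 0.45, Pmvk at -0.17 ± 0.36, Idi1 at -0.61 ± 0.54, Hspa5 at -0.97 ± 0.35 and Dnajb1 at -1.10 ± 0.31.

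Over all genes, 1653 of 14506 changed at 3 weeks, 510 higher and 1143 lower, and 4289 had an unadjusted p under 0.05. The 10 largest rises were of Slfn4 (at least 43.4-fold), Slc7a11, Nupr1, Kcnab1 (4.87 ± 0.71), Ppm1e (4.84 ± 0.52), Xist (4.73 ± 1.11), Ms4a6b (at least 14.8-fold), Erfe, St8sia6 (at least 11.3-fold) and Trim15 (4.13 ± 0.85). The largest falls were of Eif2s3y (at least 193-fold), Tmprss11f (at least 8.93-fold), Kcnk10 (at least 5.62-fold), Cdkn2a (at least 4.64-fold), Cped1 (at least 4.7-fold), Olfr1026 (at least 3.69-fold), Elk3 (-3.58 ± 0.45, another probe at 1.30), Tex16 (at least 3.7-fold), Calhm4 (at least 5.22-fold) and Alg2 (-3.51 ± 0.86). The values of Xist and Eif2s3y rest on normal diet replicates 1 and 2. The groups did not overlap for 49.5% of genes, against 10% by chance. 104 of the 1653 were not well above background in a whole group, and 8 had a further probe past the threshold in the opposite direction. The median of all genes was -0.17. Quantile normalization put it at -0.01 and gave 624 higher and 785 lower. The size of the excess of falls thus depends on the scaling, while falls outnumbered rises with both.

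The 3 week count depended on the arrays in the fit. It was 479, 198 and 344 without normal diet replicates 1, 2 and 3, and 417, 218 and 843 without 3 week replicates 1, 2 and 3. It was 3503 without 7 week replicate 1 and 4416 with no 7 week array, since the model pools the spread of the arrays in it. With normal diet replicate 3 as the only control, limma called 0 genes, and 1588 had an unadjusted p under 0.05. Of the 1653 genes, 0 changed direction in any of these fits, which was nearly fixed in advance. Leaving out 7 week arrays does not alter this fold change, and genes picked for passing can hardly turn when few arrays are dropped. With the mean over a gene's probes 14 of the 1653 changed direction, and without a filter on dim probes 3 did. Of 68 genes that the rule for named genes took and that passed, 25 kept their call without each array in turn, among them Erfe, Cth, Lyz2, Mmp9, Uqcr10, Rpl38 and Mrps21. Slc7a11, Nupr1, Socs3, Atp5k and Rps21 did not.

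After 7 weeks of low iron diet, some erythropoietin response genes and some immediate early genes were higher than on normal diet, and many G2 and M phase genes were lower. Many cytosolic ribosomal protein genes passed as higher, but only 15 of 82 lay under 20% of the saturation value, and 5 of those 15 rose. All list calls at 7 weeks were lost with an estimated correlation (adjusted p from 0.581 to 0.889). Socs3 (7.62 ± 0.52, adjusted p = 4.28e-04) and Erfe (4.61 ± 0.43, adjusted p = 0.00113) rose, as did Cdkn1a, the cell cycle inhibitor p21 (6.52 ± 1.01, adjusted p = 0.00384), and Slc2a1, the glucose transporter gene (6.37 ± 1.15, adjusted p = 0.00625). Slc40a1, the iron exporter, fell (-1.83 ± 0.30, adjusted p = 0.00441). Fth1 and Ftl1, the ferritin subunits that store iron, passed as higher (0.97 ± 0.24, adjusted p = 0.0169; 1.08 ± 0.25, adjusted p = 0.0143), but lay at 64% and 51.2% of the saturation value, and their signal before scaling differed by 0.16 and 0.28. Of 103 genes at 40% of that value or more, 52 passed as higher and none as lower, with a median of 0.78, and of -0.02 before scaling. Whether such bright genes rose relative to the others, or were held by a ceiling on the signal while the 75th percentile fell, was not tested. The 7 week arrays had fewer spots above background and brighter spike-ins relative to the other probes than both other groups.

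Erythropoietin and Stat5 response genes rose as a list at 7 weeks, with a shift of 1.40 (adjusted p = 8.53e-04, adjusted p = 0.581 with an estimated correlation). Of 16 members 7 rose and 2 fell (10 adjusted over the list alone), led by Socs3, Erfe, the signalling inhibitor Spry1 (4.41 ± 0.65) and Socs2 (4.21 ± 0.58). The receptor gene Epor was at -0.85 ± 0.30 (adjusted p = 0.0566). Immediate early genes rose, with a shift of 1.41 (adjusted p = 0.009, adjusted p = 0.622 with an estimated correlation): 5 of 13 rose and 1 fell (6 adjusted over the list alone), led by Jun (3.95 ± 0.81), Egr1 (3.22 ± 0.37), Ier3 (3.19 ± 0.42) and Fosb (2.87 ± 0.28). That call ended without 7 week replicate 1. Integrated stress response genes rose, with a shift of 0.82 (adjusted p = 0.00374, adjusted p = 0.889 with an estimated correlation), 4 of 32 rising (1 adjusted over the list alone): Nupr1 (7.88 ± 1.37), Gdf15 (4.69 ± 1.49), Slc7a11 (at least 4.78-fold) and Cth (1.74 ± 0.50). That call also ended without 7 week replicate 1. Gdf15 lay at 6.23 on that array and at -0.24 and 1.38 on 7 week replicates 2 and 3, against a normal diet mean of -2.24. Trib3, Chac1 and Ddit3 were at 2.25 ± 1.66, 1.26 ± 1.26 and 1.77 ± 1.19, and none passed. On 7 week replicate 1 they lay at 9.224, 4.404 and 9.062. On 7 week replicates 2 and 3 Trib3 lay at 1.305 and 3.364, Chac1 at -1.115 and 1.653, and Ddit3 at 3.868 and 4.159. The normal diet means of Trib3, Chac1 and Ddit3 were 2.386, 0.391 and 3.93, so their values at 7 weeks rest mostly on replicate 1. Atf4 was at 0.06 ± 0.40 (another probe at -1.08) and Eif2ak1 at -0.05 ± 0.50, and neither passed by its chosen probe.

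Of 50 G2 and M phase genes 33 fell and none rose at 7 weeks (34 adjusted over the list alone), with a list shift of -1.0 (adjusted p = 6.07e-07, adjusted p = 0.729 with an estimated correlation). Cbx5 (-4.04 ± 0.84), the spindle kinase gene Ttk (-3.70 ± 0.54), the kinetochore gene Ndc80 (-3.11 ± 0.60) and the mitosis phosphatase gene Cdc25c (-2.93 ± 0.55) led. Of 42 S phase genes 16 fell and none rose (17 adjusted over the list alone), with a shift of -1.27 (adjusted p = 1.13e-04, adjusted p = 0.889 with an estimated correlation), led by the cyclin gene Ccne2 (-3.65 ± 0.60), the replication gene Cdc45 (-3.25 ± 0.58), Cdca7 (-3.16 ± 0.89) and Slbp (-3.04 ± 0.70). At 3 weeks these lists had not passed (adjusted p = 0.894 and 0.181), with 3 of 50 and 2 of 42 lower (0 and 1 adjusted over the list alone): Tmpo (-1.09 ± 0.27, another probe at 0.90), Cks1b (-1.05 ± 0.23), Birc5 (-0.85 ± 0.23), Blm (-1.41 ± 0.28) and E2f8 (-1.26 ± 0.35). The G2 and M shift at 3 weeks was -0.07, and 0.32 with quantile normalization (adjusted p = 0.00364, with a range of 0.00364 to 0.992 over its alternatives). Among p53 targets, which did not pass as a list at 7 weeks (adjusted p = 0.0738, 4 of 17 rose and 1 fell, 6 adjusted over the list alone), Cdkn1a, Phlda3 (3.79 ± 1.09), Zmat3 (3.19 ± 0.86) and Aen (2.08 ± 0.38) rose.

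Cytosolic ribosomal proteins rose as a list at 7 weeks, with a shift of 1.11 (adjusted p = 4.34e-19, adjusted p = 0.581 with an estimated correlation): 52 of 82 rose and none fell (57 adjusted over the list alone), led by Rpl39l (4.01 ± 0.72, well above background on 1 of 3 normal diet arrays), Rpl19 (1.54 ± 0.23) and Rpl26 (1.34 ± 0.25). Oxidative phosphorylation genes rose with a shift of 0.93 (adjusted p = 6.07e-07, adjusted p = 0.866 with an estimated correlation): 23 of 75 rose and 2 fell (26 adjusted over the list alone), Atp5j2 (2.02 ± 0.34) and Ndufa7 (1.76 ± 0.27) among the rises and Sdhd (-1.34 ± 0.33) among the falls. Random lists matched on brightness had medians of 0.52 and -0.12, and with quantile normalization the shifts were 0.34 and 0.43. Among members under 20% of the saturation value, 5 of 15 and 15 of 63 rose, with medians of 0.43 and 0.62. Rpl19 and Rpl26 lay at 24.9% and 22.6% of that value and differed by 0.74 and 0.54 before scaling. Of 291 genes at 20% to 40% of it, 69 passed as higher and 14 as lower. Their median was 0.29, and -0.51 before scaling, so a ceiling on the signal was not separated from a rise for the brighter members. Mitochondrial ribosomal proteins did not pass (adjusted p = 0.431): 5 of 77 rose and 9 fell (4 adjusted over the list alone), the largest changes being falls of Mrps5 (-1.72 ± 0.51), Mrps31 (-1.42 ± 0.34), Mrpl3 (-1.39 ± 0.45) and Mrps30 (-1.35 ± 0.29).

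The globin list passed as higher at 7 weeks, with a shift of 1.02 at the edge of the threshold (adjusted p = 0.0496, adjusted p = 0.581 with an estimated correlation). 16 of 22 alternatives ended the call, among them leaving out either of normal diet replicates 1 and 2, any 3 week array, or 7 week replicate 2 or 3. Of 7 members 2 rose (4 adjusted over the list alone), Hbb-b2 (1.01 ± 0.25) and Hbb-bt (0.85 ± 0.25), and Hba-a1 was at 0.76 ± 0.26 (adjusted p = 0.0516). The list's median of 0.76 lay within the central 95% of random lists of like brightness (-0.43 to 0.94). Its 4 bright members lay at 69.5% to 78.6% of the saturation value, and their signal before scaling differed by -0.10 to 0.20. Alas2 (0.84 ± 0.26, adjusted p = 0.039) and Fech, which inserts iron into heme (0.69 ± 0.23, adjusted p = 0.049), passed as higher, but lay at 63.4% and 41.9% of that value and were at -0.02 and -0.07 with quantile normalization. The heme list did not pass (adjusted p = 0.0697, 2 of 13 rose, 0 adjusted over the list alone). In the iron list (adjusted p = 0.846, 3 of 23 rose and 3 fell, 6 adjusted over the list alone) Exoc6 (-1.66 ± 0.48) and the iron importer gene Slc11a2 (-1.36 ± 0.26) fell with Slc40a1. Tfrc was at 0.68 ± 0.43 (adjusted p = 0.247), while another of its probes was at -1.68, past the threshold. In the iron-sulfur cluster list (adjusted p = 0.896) 1 of 23 passed as higher, Glrx5 (0.91 ± 0.26), and 3 fell, among them Nubp2 (-1.82 ± 0.42) and the desulfurase gene Nfs1 (-1.37 ± 0.29), with 4 adjusted over the list alone. Glrx5 lay at 66.3% of the saturation value and differed by 0.11 before scaling.

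**Figure D2:**
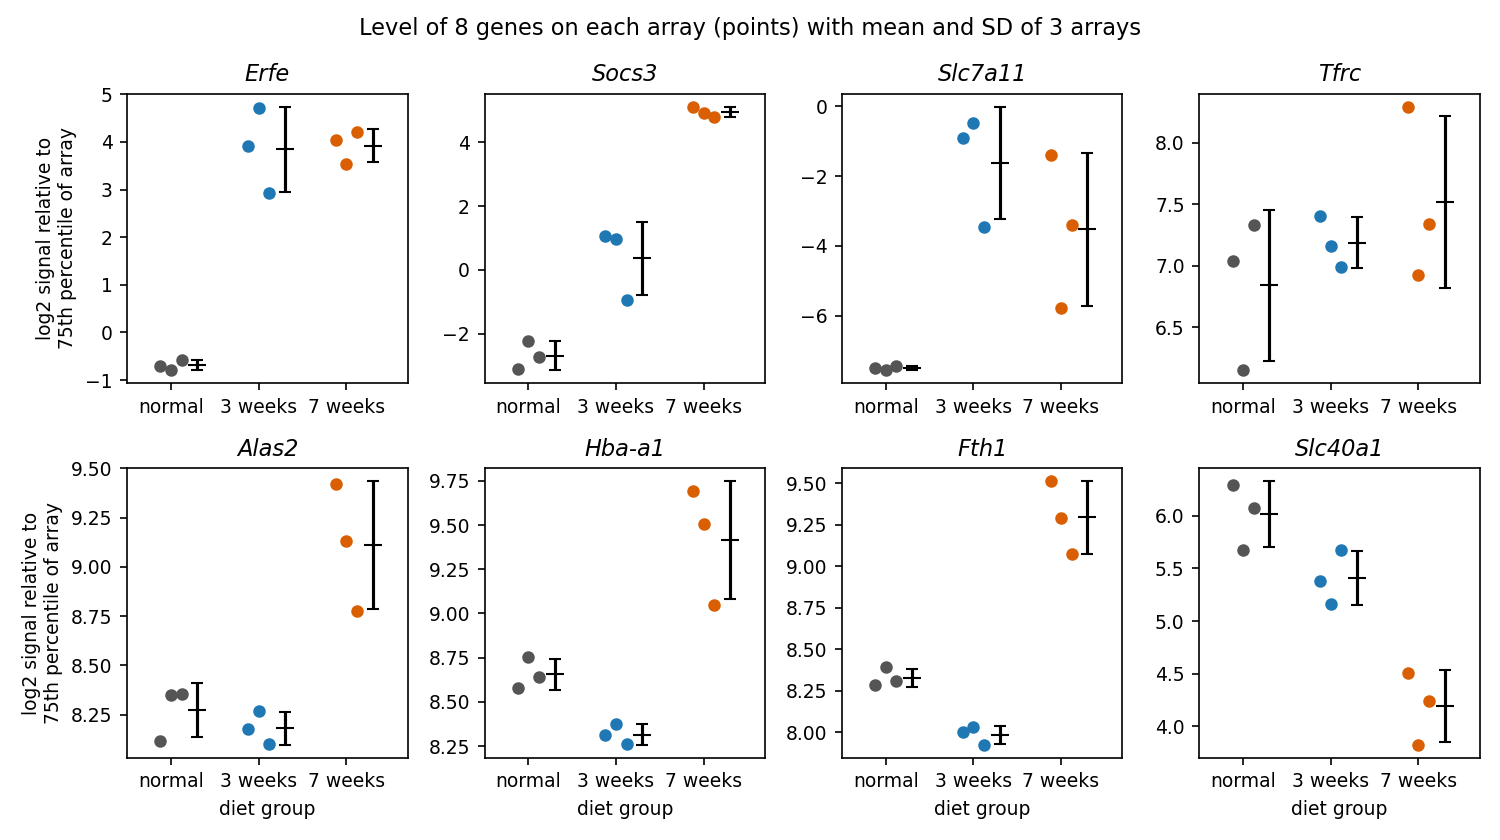
Level of 8 genes on each of 3 arrays per diet group (points), as log2 signal relative to the array's 75th percentile, with the group mean and SD (bars, n = 3); each panel has its own vertical axis, which does not start at 0. Erfe was 4.54 higher at 3 weeks and 4.61 higher at 7 weeks than on normal diet, and Slc40a1 was at -0.61 and -1.83 against it.

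Mitophagy and autophagy genes did not pass as a list at 7 weeks (adjusted p = 0.72, shift of -0.10). Of 45 members 2 rose and 8 fell (6 adjusted over the list alone), with falls of the autophagy genes Wipi1 (-2.38 ± 0.50, adjusted p = 0.00979) and Ulk2 (-2.20 ± 0.39, adjusted p = 0.00586) and of the mitophagy receptor gene Fundc1 (-1.99 ± 0.44, adjusted p = 0.0118). Bnip3l was at 0.01 ± 0.27, lay at 42.6% of the saturation value and differed by -0.80 before scaling. The 103 genes at 40% of that value or more had a median of 0.78, and of -0.02 before scaling. Glycolysis genes passed as higher as a list, with a shift of 0.52 (adjusted p = 0.0251, adjusted p = 0.729 with an estimated correlation). That call ended without 7 week replicate 3. The glycolysis list's median of 0.252 lay within the central range of random lists of like brightness (-0.867 to 0.458). Of 17 members 6 rose and none fell (6 adjusted over the list alone): Slc2a1, Pfkp (3.98 ± 0.45, another probe at -0.19), Aldoa (1.76 ± 0.33) and Pgam1 (1.69 ± 0.38) led. Among hypoxia-inducible genes (adjusted p = 0.473, 4 of 18 rose and 2 fell, 7 adjusted over the list alone) Slc2a1, Ankrd37 (3.99 ± 0.61) and Vegfa (3.95 ± 0.60) rose and P4ha1 (-2.50 ± 0.52, another probe at -0.26) fell. The list's median, -0.41, and mean, 0.39, differ in sign. Among antioxidant genes (adjusted p = 0.0697, 6 of 23 rose and 3 fell, 11 adjusted over the list alone) Slc7a11 and Srxn1 (1.55 ± 0.45) rose and Gclc (-1.42 ± 0.29) and the regulator gene Nfe2l2 (-1.33 ± 0.41) fell. Hmox1 was at 0.71 ± 0.39 and Bach1 at -0.80 ± 0.48.

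Among cell type markers at 7 weeks, the mast cell, basophil and eosinophil list fell, with a shift of -3.39 (adjusted p = 0.0496, adjusted p = 0.866 with an estimated correlation), through Prg2, the eosinophil major basic protein gene (-7.37 ± 1.39, adjusted p = 0.00697), and Epx, by at least 3.79-fold (-4.01 ± 1.16, adjusted p = 0.0315), of 6 members (5 adjusted over the list alone). The list's median was -3.65 as fitted and -1.94 with the 4 members that were dim in a whole group set to their bound. That call ended without normal diet replicate 2 or without any 7 week array. In the monocyte and macrophage list (adjusted p = 0.294) 5 of 15 fell and none rose (5 adjusted over the list alone), among them the macrophage genes Mrc1 (-2.30 ± 0.54), Mertk (-2.14 ± 0.65), Vcam1 (-1.99 ± 0.32) and Adgre1 (-1.75 ± 0.27). Neutrophil, B lineage, megakaryocyte, and T and NK cell lists did not pass (adjusted p = 0.896, 0.846, 0.896 and 0.0567), each with 1 rise and, but for the last, 1 fall (1, 0, 2 and 1 adjusted over the list alone). Elane (2.60 ± 0.42), Cd79a (1.28 ± 0.38), Gp6 (3.68 ± 0.98) and Cd4 (1.68 ± 0.42, another probe at -0.10) rose, and Chil3 (-1.31 ± 0.40), Ms4a1 (-1.26 ± 0.38) and Gp9 (-1.90 ± 0.52) fell. Lck was at -0.96 ± 0.37.

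Erythroid transcription factors did not pass at 7 weeks (adjusted p = 0.896), with falls of Sox6 (-2.02 ± 0.44) and Ldb1 (-1.40 ± 0.35) among 16 (2 adjusted over the list alone). Gata1 was at 0.10 ± 0.30 and Klf1 at -0.08 ± 0.31. Red cell membrane genes (adjusted p = 0.642, 5 of 24 rose and 4 fell, 9 adjusted over the list alone) had rises of Sptb (2.11 ± 0.42) and Bpgm (1.04 ± 0.32) and a fall of the urea transporter gene Slc14a1 (-2.27 ± 0.25). Bpgm lay at 36.3% of the saturation value and differed by 0.24 before scaling. Among progenitor genes (adjusted p = 0.846) Itga4 fell (-1.21 ± 0.31), 1 of 15 (0 adjusted over the list alone), and Lmo4 was at -1.15 ± 0.53 (another probe at 0.20). Interferon-stimulated genes (adjusted p = 0.394) had 2 rises among 18, including that of the nucleic acid sensor gene Zbp1 (1.79 ± 0.39), and no fall (2 adjusted over the list alone). Cholesterol synthesis genes (adjusted p = 0.473) had 2 rises and 2 falls among 20 (4 adjusted over the list alone), with Hsd17b7 (1.35 ± 0.39) and Mvk (1.36 ± 0.40, but -1.48 by another probe) higher and Fdft1 (-2.01 ± 0.33, another probe at -0.35) and Nsdhl (-1.61 ± 0.45) lower. Among heat shock genes (adjusted p = 0.966) Bag3 rose (2.57 ± 0.52) and Dnajb1 (-1.37 ± 0.31) and Dnaja1 (-0.75 ± 0.24) fell, of 12 (3 adjusted over the list alone).

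Over all genes, 4278 of 14506 changed at 7 weeks, 1559 higher and 2719 lower, and 6258 had an unadjusted p under 0.05. The median of all genes was -0.26, and 0.01 with normexp background correction. The 10 largest rises were of Nupr1, Socs3, the purine enzyme gene Gmpr (7.08 ± 0.76), the cytidine deaminase gene Cda (6.72 ± 0.88), Cdkn1a, Ndrg4 (at least 49.3-fold), Atp6v0d2 (at least 50.1-fold), Slc2a1, Tubb3 (6.25 ± 0.86) and Ppm1e (6.16 ± 0.52). The largest falls were of the aldehyde dehydrogenase gene Aldh1a7 (-7.84 ± 1.03), Prg2, Eif2s3y (at least 48.5-fold, resting on normal diet replicates 1 and 2), Stard10 (-6.71 ± 1.03), Cd209f (at least 30.8-fold), Psd3 (at least 25.2-fold), Sh2d4a (at least 15.2-fold), the sulfide oxidase gene Sqor (-5.67 ± 0.49), Aldh3b2 (at least 22.4-fold) and Dlg3 (-5.55 ± 0.62). Aldh1a7 and Dlg3 were well above background on 1 of the 3 arrays at 7 weeks and Prg2 and Stard10 on 2, so the sizes of these falls are uncertain. The groups did not overlap for 47.4% of genes, against 10% by chance. 525 of the 4278 were not well above background in a whole group, and 40 had a further probe past the threshold in the opposite direction.

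The 7 week count was 1739 without normal diet replicate 1 and 2148 without replicate 3, and 2819 without the 3 week arrays. With normal diet replicate 3 as the only control it was 1, with 3047 at an unadjusted p under 0.05. Without a filter on dim probes it was 6939, with 4178 higher and 2761 lower (60.2% higher against 36.4%). Kdm5d, not well above background on any array, lay at -7.52, -7.56 and -7.44 on normal diet and at -5.27, -5.76 and -6.06 at 7 weeks. A probe without signal can thus have a higher scaled value at 7 weeks, and how far this made the excess was not tested. Of the genes that the rule took and that passed, 59 kept their call without each array in turn, among them Erfe, Socs3, Nupr1, Cdkn1a, Slc2a1, Slc40a1 and Ttk. Alas2, Fech, Fth1, Ftl1, Hbb-b2, Hbb-bt and Slc7a11 did not.

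**Figure D3:**
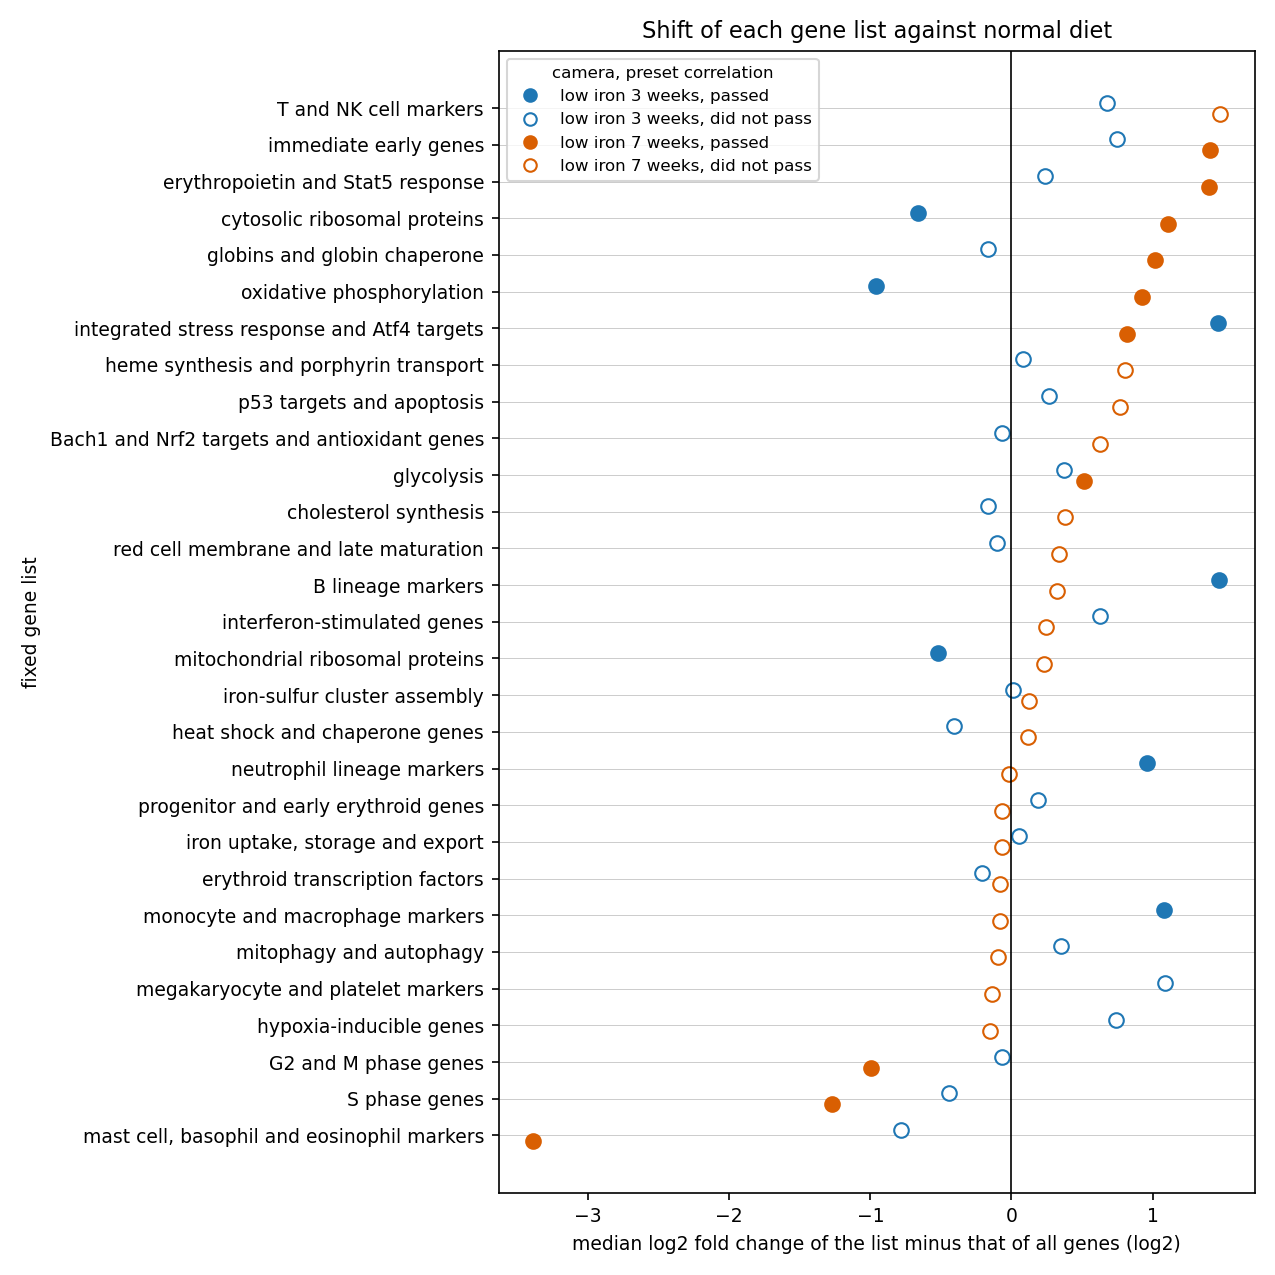
Median log2 fold change of each of 29 gene lists minus that of all genes (horizontal axis, log2) at 3 weeks (blue) and 7 weeks (orange) of low iron diet against normal diet; filled points passed camera with a preset correlation and open points did not. Oxidative phosphorylation lay at -0.96 at 3 weeks and 0.93 at 7 weeks, and no list passed with an estimated correlation.

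Between 3 and 7 weeks of low iron diet, the respiratory chain and ribosomal lists were higher at 7 weeks and the cell cycle and macrophage lists lower by camera with the preset correlation. These calls were lost with an estimated correlation (adjusted p from 0.435 to 0.872). This comparison does not involve the normal diet arrays' levels. Oxidative phosphorylation rose by a shift of 2.06 (adjusted p = 7.69e-18, 55 of 75 higher and 1 lower, 58 adjusted over the list alone), with Atp5k (3.49 ± 0.44), Uqcr10 (3.34 ± 0.30), Ndufa7 (3.17 ± 0.27) and Ndufa3 (3.13 ± 0.28) leading. Cytosolic ribosomal proteins rose by 1.87 (adjusted p = 1.81e-28, 75 of 82 higher and none lower, 77 adjusted over the list alone) and mitochondrial ones by 0.86 (adjusted p = 0.00379, 24 of 77 higher and 5 lower, 29 adjusted over the list alone). The adjusted p with an estimated correlation was 0.729, 0.435 and 0.872 for these 3 lists, and the last call ended without 7 week replicate 3. Rpl39l rose at least 13-fold, and Rpl38 (3.11 ± 0.28), Mrpl54 (2.93 ± 0.39) and Mrpl52 (2.90 ± 0.52) rose. With quantile normalization the shifts of the respiratory and cytosolic ribosomal lists were 1.28 and 0.73, and 43 of 63 and 10 of 15 members under 20% of the saturation value were higher.

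The globin list passed as higher at 7 than at 3 weeks, by a shift of 1.23 (adjusted p = 0.0136, adjusted p = 0.435 with an estimated correlation; 5 of 7 higher, 5 adjusted over the list alone), with Hbb-y (1.93 ± 0.65), Hbb-b2 (1.28 ± 0.25), Hba-a1 (1.10 ± 0.26) and Hbb-bt (1.08 ± 0.25). With quantile normalization the list did not pass, and Hba-a1 and Hbb-bt were at -0.02 and -0.04. The signal of its 4 bright members before scaling differed by 0.08 to 0.32, and the list's median of 1.10 lay within the central 95% of random lists of like brightness (-0.09 to 1.49). Of the 103 genes at 40% of the saturation value or more, 90 passed as higher, while Hbb-y lay at 0.302%. Fth1 (1.31 ± 0.24, adjusted p = 0.00331), Ftl1 (1.29 ± 0.25, adjusted p = 0.00471) and Alas2 (0.93 ± 0.26, adjusted p = 0.021, but -0.24 with quantile normalization) passed as higher, with 0.34, 0.33 and -0.03 before scaling. Slc40a1 fell (-1.22 ± 0.30, adjusted p = 0.0123). Erfe was at 0.07 ± 0.43 (adjusted p = 0.907) and Tfrc at 0.33 ± 0.43, with other probes past the threshold in the opposite direction. Trib3, Chac1, Ddit3, Atf4 (another probe at -3.14), Eif2ak1, Hmox1, Bach1, Epor and Gata1 did not pass. Nor did Klf1 (0.20 ± 0.31) and Bnip3l (0.13 ± 0.27), which were at -0.77 and -1.0, past the threshold, with quantile normalization. G2 and M phase genes fell by a shift of -0.97 (adjusted p = 4.29e-05, adjusted p = 0.872 with an estimated correlation; 27 of 50 lower and 4 higher, 33 adjusted over the list alone), led by Cdc25c (-4.88 ± 0.55) and Dlgap5 (-3.74 ± 0.32). S phase genes fell by -0.96 (adjusted p = 0.0325, adjusted p = 0.872 with an estimated correlation; 6 of 42 lower and 1 higher, 4 adjusted over the list alone), led by Cdc45 (-5.20 ± 0.58), a call that ended without 3 week replicate 1 or 3 or without 7 week replicate 1.

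The monocyte and macrophage list fell between 3 and 7 weeks by a shift of -1.96 (adjusted p = 5.77e-04, adjusted p = 0.729 with an estimated correlation; 10 of 15 lower and none higher, 10 adjusted over the list alone), led by Lyz2 (-3.76 ± 0.48), Mrc1 (-3.21 ± 0.54), Mertk (-2.90 ± 0.65) and Ccr2 (-2.73 ± 0.61). Over all genes 5391 of 14506 differed, 2546 higher and 2845 lower at 7 weeks, with 599 not well above background in a whole group, 109 with a further probe in the opposite direction, and 48.4% without overlap of the groups. Which direction was in excess depended on the processing: normexp gave 3082 higher and 2595 lower, no filter on dim probes 4723 and 2818, and quantile normalization 2259 and 3226. The count was 3544 without 3 week replicate 3. The largest rises were of Cda (7.11 ± 0.88), Atp6v0d2 (6.50 ± 0.75), Rmrp (at least 19.9-fold), Ndrg4 (5.68 ± 1.42) and Ntrk2 (5.64 ± 0.37), and the largest falls of Aldh1a7 (-7.66 ± 1.03), Stard10 (-6.50 ± 1.03), Cd209f (at least 30.1-fold), Gpc4 (at least 17.6-fold) and the platelet chemokine gene Ppbp (-5.91 ± 1.37). In the dimmer group Aldh1a7, Atp6v0d2 and Ndrg4 were well above background on 1 of 3 arrays and Cda, Stard10 and Ppbp on 2, so the sizes of these changes are uncertain.

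The calls at 3 and 7 weeks overlapped in 121 genes higher at both times and 323 lower at both, where independent lists of those sizes would share 54.8 and 214. A further 206 passed in opposite directions, against 218 for independent lists. Simulated unchanged groups against the same controls shared 0.01 on average in both directions together. Almost no gene passes without an effect, so this value does not measure the part of the overlap owed to shared controls. The 444 genes shared in direction became 70, 62 and 81 without normal diet replicates 1, 2 and 3, 111, 84 and 277 without 3 week replicates 1, 2 and 3, and 916 without 7 week replicate 1. Across the 14506 genes, which are not independent, the fold changes at both times correlated at r = 0.181 (Spearman 0.14). In 100 simulations with shared controls and no effect, r was 0.502 (0.471 to 0.528). The covariance was 0.217, against 0.152 simulated, a difference of 0.0646. The simulations gave every group the same spread, while normal diet arrays correlated at 0.981 to 0.987 and 7 week arrays at 0.909 to 0.958. The simulated values follow from that setting, so they do not give the part owed to these controls, and the differences decide nothing. The covariance was 0.127 without 7 week replicate 1, 0.138 without 3 week replicate 2 and 0.151 without normal diet replicate 1, all below the simulated value, which was not made again for these fits. It reached 0.317 without 3 week replicate 3. The jackknife SD of r over the arrays was 0.145. With 3 control arrays they could not be split into 2 sets of at least 2, so the part of the overlap owed to shared controls was not separated by splitting them.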

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

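The tests of brightness, saturation, gene span, slide, other cells and sex below were chosen after the results were seen; the test of the difference between 7 and 3 weeks and the splits of the arrays were planned.

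Levels differed between the 7 and 3 week groups for 5391 genes by the test of the difference itself. Of all genes, 206 passed in opposite directions against normal diet at both times, against 218 for independent lists. Of these, 205 also passed in that test, which nearly follows from how they were picked. Both times share the same normal diet arrays, so this test sets the 7 week arrays against the 3 week arrays. Slide, scan and age therefore cannot be told apart from the time on the diet in it. Lists that passed camera with the preset correlation in this comparison, with their medians, were globins (1.10), oxidative phosphorylation (1.93), mitochondrial ribosomal proteins (0.73), cytosolic ribosomal proteins (1.74), S phase genes (-1.08), G2 and M phase genes (-1.09) and monocyte and macrophage markers (-2.09). With an estimated correlation 0 lists passed (lowest adjusted p = 0.435). Of the fixed set of genes and of the named genes among those 205, the test of the difference gave Alas2 (0.93), C1qa (-2.42), Exoc6 (-3.43), Fth1 (1.31), Ftl1 (1.29), Hba-a1 (1.10), Ms4a1 (-2.71), Ndufa3 (3.13), Ndufa7 (3.17), Rpl26 (2.29), Rpl36 (3.09), Rpl38 (3.11), Rps15a (2.85, another probe at -0.61), Slc40a1 (-1.22) and Uqcr10 (3.34). With quantile normalization Alas2 and Hba-a1 were at -0.24 and -0.02. Alas2, Fth1, Ftl1 and Hba-a1 lay at 63.4%, 64%, 51.2% and 76.6% of the saturation value, and before scaling differed by -0.03, 0.34, 0.33 and 0.14. Probes without a gene name, which entered no comparison of the report, changed as well: of 15962 tested, 2525 at 3 weeks (441 higher and 2084 lower), 4941 at 7 weeks (2854 and 2087) and 6465 between 7 and 3 weeks (4585 and 1880), where named genes had the excess in the other direction in the last 2. Whether higher scaled values of dim probes on the 7 week arrays added to that was not tested.

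Of 82 cytosolic ribosomal protein and 75 oxidative phosphorylation genes, 38 and 40 were lower at 3 weeks and 52 and 23 higher at 7 weeks than on normal diet, list calls lost with an estimated correlation (adjusted p from 0.581 to 0.866). On scaling that depends on brightness, 4 of 4 list medians lay outside the central 95% of random lists of like brightness. Those lists moved in part the same way, at -0.52 and 0.52 for the cytosolic ribosomal list and at -0.56 at 3 weeks for oxidative phosphorylation. Among members under 20% of the saturation value, 15 and 63, the medians at 3 and 7 weeks (-0.99 and 0.43, -1.13 and 0.62) were outside as well. The random lists took genes as independent, while the members varied together (estimated correlations of 0.35 and 0.49). Both lists were also picked for their shifts. The range is thus too narrow to decide on such scaling as the whole cause. With lists matched on brightness and span, 4 of 4 medians were outside, with the same limits, so a trend with gene span stays undecided. Slide and scan cannot be told apart from the diet, since 0 slides held more than 1 group, and the 7 week arrays had brighter spike-ins relative to the other probes. An effect of the diet or of age stays open and was not tested.

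Of 17 neutrophil, 15 monocyte and macrophage, and 11 B lineage markers 2, 4 and 2 were higher at 3 weeks, list calls lost with an estimated correlation (adjusted p = 0.835, 0.728 and 0.728). On scaling that depends on brightness, 3 of 3 list medians lay outside the central 95% of random lists of like brightness. The random lists took genes as independent, while the members varied together (estimated correlations of 0.5, 0.24 and 0.6). This does not decide on such scaling as the whole cause. Other cells in the sorted fraction may have added this RNA, although the sort for erythroblasts should remove them: the brighter members rose less than the dimmer in all 3 lists (medians of 0.17, 0.34 and 1.30 against 1.29, 0.99 and 1.65; 0.35 for the brighter together), which decides nothing, as a small share of RNA shows less in a bright gene, so they cannot be told apart from a change within erythroblasts. S100a8, S100a9 and Camp, abundant neutrophil genes chosen after their values were seen, were at -1.01, -0.68 and -0.02, while Lyz2 was at 3.59, and their high level on normal diet would hide a small share. All 17, 15 and 11 measured members were well above background on all normal diet arrays, and 0 of them stood in another of the lists.

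Normal diet replicates 1 and 2 had high Eif2s3y and Ddx3y and low Xist, although labelled female, and replicate 3 had Eif2s3y at -3.77, also well above background. RNA of male animals on both arrays is a candidate explanation: 2 arrays had Eif2s3y and Ddx3y well above background and both Xist probes below all 7 other arrays, while Kdm5d was not well above background on either and Uty on 1 of them. A small share of male RNA in female samples is argued against, since the highest Xist of these arrays lay below the lowest of the others by a log2 difference of -2.76 for the probe with the smaller gap. Whether samples or labels were exchanged was not tested, and a sex difference stays open beside the diet in both comparisons with normal diet. Without genes on chromosomes X and Y, 1616 and 4124 genes changed at 3 and 7 weeks, which removes sex-linked genes and not the effect of sex on other genes.

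The 6 arrays of a comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, 1 split of 10 reached the real count in each comparison, the real one itself: 1653, 4278 and 5391, with 0, 0 and 1 as the highest of the others. For gene lists, 7, 6 and 8 of 10 splits reached the real counts of 7, 10 and 7, and the highest others were 13, 17 and 17, so list calls with the preset correlation were as frequent in splits that mix the groups.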

How the results depend on the processing

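The alternatives with normal diet replicate 3 alone and without genes on chromosomes X and Y were chosen after seeing the data; slide as a block was not run, since each slide holds 1 group. The correlation of fold changes stayed within 0.107 to 0.275. At 3 weeks, genes numbered 4416 with only the arrays of the 2 groups, where fewer samples set the spread, and 0 in limma with normal diet replicate 3 alone (1588 at an unadjusted p under 0.05), where the lone sample is assumed to vary like the other groups; leaving out each array gave 198 to 3503. At 7 weeks they numbered 6939 without a filter, 2819 with only the 2 groups and 1 with replicate 3 alone, and 1739 to 5210 on leaving out each array; between 7 and 3 weeks that range was 3544 to 6489. The overlap was 0 with replicate 3 alone (354 at an unadjusted p under 0.05) and 62 to 916 on leaving out each array. Gene lists numbered 12 at 3 weeks with quantile normalization, 6 at 7 weeks with normexp and 5 without a filter; camera with an estimated correlation gave 0 in all 3 comparisons (0, 1 and 2 at an unadjusted p under 0.05), and fry gave 4, 5 and 8. With the replicate number as a replicate block, genes numbered 1401, 4063 and 5245, where equal numbers correlated across groups at r of -0.172 to 0.286 and others at -0.266 to 0.245; 4 of 9 equal pairs exceeded 0.1, which shows no clear pairing.

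Reversed with quantile normalization were the G2 and M phase list at 3 weeks (0.32), Alas2 (-0.019) and Fech (-0.074) at 7 weeks. Between 7 and 3 weeks Alas2 (-0.24), Bnip3l (-1.0), Gapdh (-0.18), Hba-a1 (-0.022), Hbb-bt (-0.037), Klf1 (-0.77), Tspo2 (-0.026) and Urod (-0.0645) reversed. Reversed with the mean over probes were Mvk at 7 weeks (-0.060) and, between 7 and 3 weeks, Alas1 (0.15), Gapdh (-0.057) and Hk1 (-0.23). The interferon list between 7 and 3 weeks, with a shift of -0.26 in the main fit, ranged from -1.43 without 7 week replicate 1 to 0.57 without 7 week replicate 2. Without 7 week replicate 1 it counts as reversed only by camera's direction, which was up in the main fit (camera adjusted p = 0.98), as its shift was negative in both. The cause of these reversals was not tested. Of 7054 values of 357 results for genes that the rule took, 6125 kept direction and side of the threshold, 865 lost a call, 50 gained one and 14 reversed; of 1911 values of 87 list results these were 1773, 80, 56 and 2. On the 7 week arrays 45.2% to 53.6% of spots were well above background, which limits what can be seen for dim genes.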

Other observations

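All tests behind the values in this part were planned, except the random lists of like brightness, chosen after the results were seen; the genes were named by the rule.

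Members of several lists not described above differed between 7 and 3 weeks, while the lists did not pass camera. Of all genes 37.2% differed in this comparison. Of 23 antioxidant genes 9 were higher and 2 lower at 7 weeks (12 adjusted over the list alone, adjusted p = 0.205), with Srxn1 (2.98 ± 0.45), Txn1 (1.78 ± 0.25) and Sod1 (1.64 ± 0.23) rising and Nqo1 (-1.62 ± 0.37) falling. Txn1 and Sod1 lay at 32.3% and 44.5% of the saturation value and differed by 0.82 and 0.68 before scaling. Of 16 erythropoietin and Stat5 response genes 7 were higher and none lower (7 adjusted over the list alone, adjusted p = 0.0942), with Socs3 (4.57 ± 0.52), Spry1 (4.43 ± 0.65), Socs2 (2.93 ± 0.58) and Socs1 (2.34 ± 0.45) rising. Of 45 mitophagy and autophagy genes 4 were higher and 10 lower (14 adjusted over the list alone, adjusted p = 0.26; median of -0.75, below the central 95% of random lists of like brightness, -0.47 to 0.40), with falls of the lipid kinase gene Pik3c3 (-2.82 ± 0.59), of Nbr1 (-2.26 ± 0.76), of Atg10 (-2.22 ± 0.67) and of Atg4b (-1.85 ± 0.31). Of 32 integrated stress response genes 6 were lower and none higher (2 adjusted over the list alone, adjusted p = 0.26), among them the proline synthesis gene Aldh18a1 (-2.02 ± 0.38), Shmt2 (-1.68 ± 0.35) and the serine synthesis gene Psat1 (-1.33 ± 0.42).

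Of 17 neutrophil lineage markers 2 were higher and 7 lower at 7 than at 3 weeks (9 adjusted over the list alone, adjusted p = 0.242), with Mmp9 (-4.03 ± 0.52) and Ngp (-3.34 ± 0.50) falling, and of 11 B lineage markers 1 was higher and 4 lower (6 adjusted over the list alone, adjusted p = 0.141), with Ms4a1 (-2.71 ± 0.38) falling and Cd79a (1.69 ± 0.38) rising. The 22 lists that did not pass in this comparison had adjusted p from 0.0942 to 0.98.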
